A study of Mus musculus with 36 samples.

How the data were processed

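BRB-seq libraries had been made from polyadenylated RNA of Nf1-null mouse astrocytes carrying a dominant-negative p53, grown in medium with serum. The labels give each library a lot, a sex and a replicate number, which put the 36 libraries into 10 lines of 5 lots. Per the labels, the deposited table holds raw counts per Ensembl mouse gene, and its values were whole numbers. The submitters' processing notes name cutadapt 2.10, STAR 2.7.6a, Subread 2.0.2 and the GRCm38 genome. Whether the authors collapsed molecular identifiers is not stated, so intervals and floors cover counting error only.

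Of 46078 genes, 45229 were matched by identifier to GENCODE release M21, and the other 849 held 0.0295% of the counts. In all libraries together, 23859 genes had no count. Library totals had a median of 6.06e+06, and the floor of 3 counts was computed for each library. Mitochondrial mRNA made up 0.251 to 0.775% of a library and the 10 most abundant genes 9.16 to 11.5%. The 48 pairs of libraries of the same line differed by a chi-square of 5.63 to 24.1 per degree of freedom, and 0 pairs were identical.

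Counts were analysed with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3, and tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. For the comparison across lots, the libraries of each line were summed and the 10 sums fitted with lot and sex by edgeR's quasi-likelihood method, after its expression filter and TMM scaling. Within lots, for the test of whether the sexes differed alike in all lots, and for differences among lots of the same sex, the 36 libraries were fitted with 1 coefficient per line. Fold changes are female over male on the log2 scale, given with a standard error for most single genes. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Means and SD in CPM use TMM-scaled library sizes, except for the levels per line of Nf1, Trp53 and Xist, the Y-linked sums, the microglia and macrophage markers in lot 6, and Rps3a1 with its copies, whose CPM use library totals.

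Gene lists were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01, where at least 5 members were tested. Camera was repeated with an estimated correlation and fry was run beside it. List scores are means over a list's genes of log2 CPM, centred on each gene's mean over lines, with a prior count of 2. Score differences over 5 lots were tested by exact 2-sided sign flips, whose smallest p is 0.063. The correlation of scores had 100000 permutations. The median log2 fold change of a chromosome's genes, over genes with a mean log2 CPM of at least 4, was set against 10000 random sets. These sets held as many genes from the other chromosomes, matched on mean expression.

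The genes named were chosen by a rule fixed before the data were examined. Across lots, up to 10 autosomal genes in each direction that passed were to be named, and where fewer than 5 passed, the list was filled to 5 by smallest p among genes with a mean log2 CPM of at least 2. Within each lot, the rule took the 3 highest and 3 lowest fold changes among autosomal genes that passed, at a mean log2 CPM of at least 3. It took the 5 genes of smallest p for differences between lots, and up to 4 members of each list by p. Members of the X- and Y-linked lists, Nf1, Trp53 and a fixed set of NF-kB and STAT3 genes were always included. Predicted genes and pseudogenes were skipped. The text gives values for only part of the genes that the rule took. Among the genes always included, Socs3, Il6, Lcn2, Icam1, Ddx3x, Eif2s3y, Kdm5d and Uty have no values of their own below.

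Alternatives were another scaling, no scaling, other filters, DESeq2, limma voom with the line as a random block, libraries as replicates, no lot block, a replicate block, thinned counts, the libraries of a lot alone, and leaving out each library or lot. Replicate numbers were checked for pairing between the sexes: residual correlations between libraries of the same number ranged from -0.027 to 0.229 over 18 pairs, with 3 over 0.1, all in lot 12, and 0 of 48 pairs of other numbers exceeded 0.1. Under that cut, replicate 4 of both sexes correlated at 0.0728, 0.0892 and 0.0917 in lots 7, 8 and 11. In each line of these lots, replicate 4 also had the lowest share of mitochondrial mRNA, at 0.251 to 0.349%. A weaker pairing of these libraries is therefore not excluded. The methods were tested on simulated data with 200 genes changed between the sexes across lots, in lot 6 and in lot 7. These comparisons called 3 to 6 unchanged genes, and the test of differences between lots, over the genes changed in either lot, called 10.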

Results

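Gene expression was measured by BRB-seq, a pooled method that counts the 3' ends of polyadenylated transcripts with sample barcodes and unique molecular identifiers, in mouse astrocytes lacking Nf1 and transformed with a dominant-negative p53. The 36 libraries came from 10 lines: 1 female and 1 male line from each of 5 lots, which the labels describe as separate litters. Lots 6 and 12 had 3 libraries per line, and lots 7, 8 and 11 had 4. Library totals ranged from 4358098 to 7562901 counts, and 12654 to 14177 genes were detected per library. At these depths, 3 counts in a library corresponded to 0.397 to 0.688 CPM, that is, counts relative to the library total. The labels do not say that the libraries of a line were separate cultures, so p-values within a lot and for differences between lots measure only the spread between libraries of the same lines. With 1 line per sex and lot, differences between sexes or litters in these tests cannot be told apart from differences between single lines.

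The genes that define the model and the sex of the lines were examined before any comparison. Nf1 (chromosome 11, 79339693 to 79581612, GRCm38), whose product restrains Ras, was near the detection floor, with line means from 0.70 CPM in the lot 6 female line to 2.32 CPM in the lot 6 male line. Trp53 (chromosome 11, 69580359 to 69591873) ranged from 192 ± 8.97 CPM in the lot 6 female line (SD, n = 3) to 394 ± 62.0 CPM in the lot 7 male line (SD, n = 4). A 3' count does not show whether an upstream part of a gene was deleted, and no line with intact Nf1 or p53 was analysed here. Y-linked transcripts summed to 0 to 1.80 CPM in the 18 female libraries and to 10.6 to 61.8 CPM in the 18 male libraries, so every library carried the Y-linked signal of its label. Xist, the RNA that coats the inactive X chromosome, averaged 3.88 to 6.40 CPM in the female lines of lots 7, 8, 11 and 12. Its level varied between libraries, and lot 8 female replicate 3 had 1 count, or 0.186 CPM, where the other libraries of that line had 13 to 35 counts. Xist reached 0.433 ± 0.375 CPM (SD, n = 3) in the lot 6 female line, or 9 counts in all, and 0 to 0.0742 CPM in the male lines.

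Markers of several cell types were measured in the lines. Gja1, the main gap junction protein of astrocytes, averaged 145 CPM over the 10 lines and the intermediate filament gene Nes 90.2 CPM. The contractile gene Acta2 was more abundant, at a mean of 6086 CPM and from 1342 to 14930 CPM between lines. The collagen gene Col1a2 ranged from 9.62 to 612 CPM. Many markers of the same types were low: the median astrocyte marker averaged 0.996 CPM, with 6 of 12 over 1 CPM, the median neural progenitor marker 0.776 CPM, with 4 of 9 over 1 CPM, and the median pericyte and smooth muscle marker, the list of Acta2, 0.0207 CPM, with 2 of 8 over 1 CPM. Cd68 was the most abundant of 12 microglia and macrophage markers, at a mean of 3.25 CPM.

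The first comparison asked which genes differed between female and male lines across litters, with the lot as the independent unit (n = 5 per sex). No gene passed. Among autosomal genes with the smallest p and a higher value in female lines, Mest, an imprinted gene of the mesoderm (chromosome 6, 30723547 to 30748465), averaged 20.97 ± 15.4 CPM in female and 1.39 ± 1.26 CPM in male lines (SD, n = 5). The lysosomal protease gene Ctsd averaged 885 ± 362 and 521 ± 119 CPM, and Rsph9, which encodes a cilium component, 8.79 ± 2.04 and 2.64 ± 1.38 CPM. Saraf and Thbs3 had log2 fold changes of 0.63 ± 0.13 and 0.73 ± 0.15 (SE). In the other direction, Olfml2b averaged 5.08 ± 2.62 CPM in female and 16.0 ± 9.36 CPM in male lines, and Kitl, the ligand of the Kit receptor, 3.83 ± 1.38 and 10.2 ± 5.10 CPM (SD, n = 5). Dctd, Igfbp6 and the actin-binding Dbn1 had log2 fold changes of -0.60 ± 0.11, -1.10 ± 0.21 and -0.55 ± 0.11 (SE). Each of these 10 genes had the same sign in all 5 lots and an adjusted p of 0.695.

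Of 12010 genes tested with edgeR, 0 had an adjusted p under 0.05, against 841 with an unadjusted p under 0.05, where 600.5 would be expected by chance. Without lot 6, 581 of 12124 genes had an unadjusted p under 0.05, no excess over chance. Without 1 of the other lots, 695 to 929 did. DESeq2 called 60 genes and limma voom with the line as a random block called 412. Even Ddx3y on the Y chromosome, at a log2 fold change of -6.36 ± 0.64, had an adjusted p of 0.14. On simulated data of the same size, 40.3% of 2-fold, 79.1% of 4-fold and 92.4% of 8-fold changes were recovered. These shares hold for the spread of the simulated data. They may overstate what was recoverable in the real lines, where not even Ddx3y passed. Treating all 36 libraries as replicates gave 1269 genes, a count that takes libraries of a line for separate litters.

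**Figure D1:**
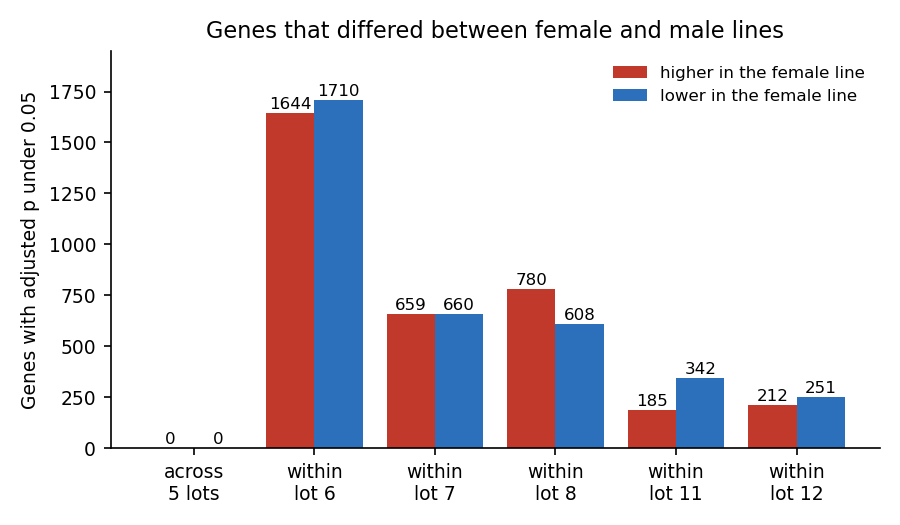
Number of genes with an edgeR adjusted p under 0.05 that were higher (red) or lower (blue) in female than in male lines, tested across the 5 lots and within each lot. No gene passed across lots, while lot 6 had 1644 higher and 1710 lower.

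Among the gene lists fixed beforehand, X-linked genes known to escape inactivation were higher in female lines across lots, with 5 of 6 members above 0 and a median log2 fold change of 0.49. Kdm6a, a histone demethylase gene of this list, averaged 5.57 ± 1.37 CPM in female and 2.98 ± 0.916 CPM in male lines (SD, n = 5). The list passed limma's camera at an adjusted p of 0.0105 with a preset correlation, but not at adjusted p = 0.795 with an estimated correlation. It also missed the threshold without lot 7 (adjusted p 0.0582) and without lot 12 (adjusted p 0.0523), and ranged from 2.67e-08 to 0.795 over the alternatives. Adjusted over the list alone, 2 members passed, and over all genes 0. Ribosomal protein genes had a median log2 fold change of -0.21, with 4 of 95 members above 0. The preset correlation gave an adjusted p of 1.59e-19 and the estimated one an adjusted p = 0.795 with an estimated correlation. The share of counts on ribosomal protein genes was 21.9 ± 2.74% in female and 24.6 ± 1.88% in male lines (SD, n = 5). It was lower in the female line in all 5 lots, with an exact 2-sided sign-flip p of 0.063, the smallest that 5 lots allow. In lot 11 the shares were nearly equal, at 25.59 ± 0.46 and 25.64 ± 0.75% (SD, n = 4). The list score was higher in the female line of that lot, by 0.012, and had an exact sign-flip p of 0.125. The share on the 10 most abundant genes was also lower in the female line in all 5 lots, at 9.598 ± 0.235% against 10.2 ± 0.606% (SD, n = 5; exact sign-flip p of 0.063). That on pseudogenes was higher in the female line in 1 of 5 lots, at 3.21 ± 0.261% against 3.54 ± 0.370% (SD, n = 5; exact sign-flip p of 0.125). Library totals, genes detected, and the shares of mitochondrial mRNA and ribosomal RNA were compared alike, with exact sign-flip p of 0.25 to 0.69. None of these p-values was adjusted, and shares of the same totals are not independent of each other. The median log2 fold change of ribosomal protein genes stayed negative under each scaling, at -0.12 with library totals alone.

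The series title concerns NF-kB and STAT3 signalling, so these lists were examined in each litter. Across lots, NF-kB targets had a median log2 fold change of -0.02 over 26 members (adjusted p 0.851, limma camera), and this median became 0.07 with library totals alone. STAT3 targets had a median of 0.24, with 16 of 22 members above 0 (adjusted p 0.143), and components of both pathways a median of 0.04 (adjusted p 0.703). Adjusted over the list alone, 0 members passed in any of these 3 lists, nor did any over all genes. Of the regulators themselves, Rela averaged 44.5 ± 6.23 and 42.5 ± 5.50 CPM in female and male lines, Nfkb1 6.30 ± 1.46 and 6.69 ± 1.16 CPM, Nfkb2 29.7 ± 8.03 and 30.8 ± 9.65 CPM, Relb 9.19 ± 3.90 and 8.61 ± 5.03 CPM, and Stat3 11.7 ± 5.63 and 8.27 ± 1.16 CPM (SD, n = 5). The cytokine receptor gene Il6st averaged 35.7 ± 19.3 CPM in female and 20.1 ± 6.73 CPM in male lines (SD, n = 5).

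The NF-kB target score differed between the sexes in opposite directions from litter to litter. The female line minus the male line was 0.13 in lot 6, -0.77 in lot 7, 0.93 in lot 8, -0.48 in lot 11 and 0.28 in lot 12, with a mean of 0.018 ± 0.669 (SD, n = 5 lots; exact sign-flip p of 1). The STAT3 target score was higher in the female line by 0.63 in lot 6, 0.41 in lot 7 and 0.15 in lot 12, and differed by -0.012 in lot 8 and -0.0072 in lot 11. Its mean difference was 0.235 ± 0.281 (SD, n = 5 lots; exact sign-flip p of 0.25). Within lots, the STAT3 target list passed limma's camera in 0 lots. In lot 6, 9 of 24 members were called higher and 3 lower (adjusted p 0.127), and in lot 7, 6 were higher and 2 lower (adjusted p 0.143). Over the 10 lines, the NF-kB and STAT3 scores had a Pearson correlation of -0.11 (permutation p 0.77) and a Spearman correlation of -0.030 (permutation p 0.947). Without the 2 lines farthest from the median NF-kB score, lot 7 male and lot 8 female, the Pearson correlation was 0.34, and 0.21 with genes at unit SD. With scores averaged over libraries, the lines left out were lot 7 male and lot 8 male, and it was -0.19. The sexes hold 5 lines each, too few for a correlation within each sex.

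**Figure D2:**
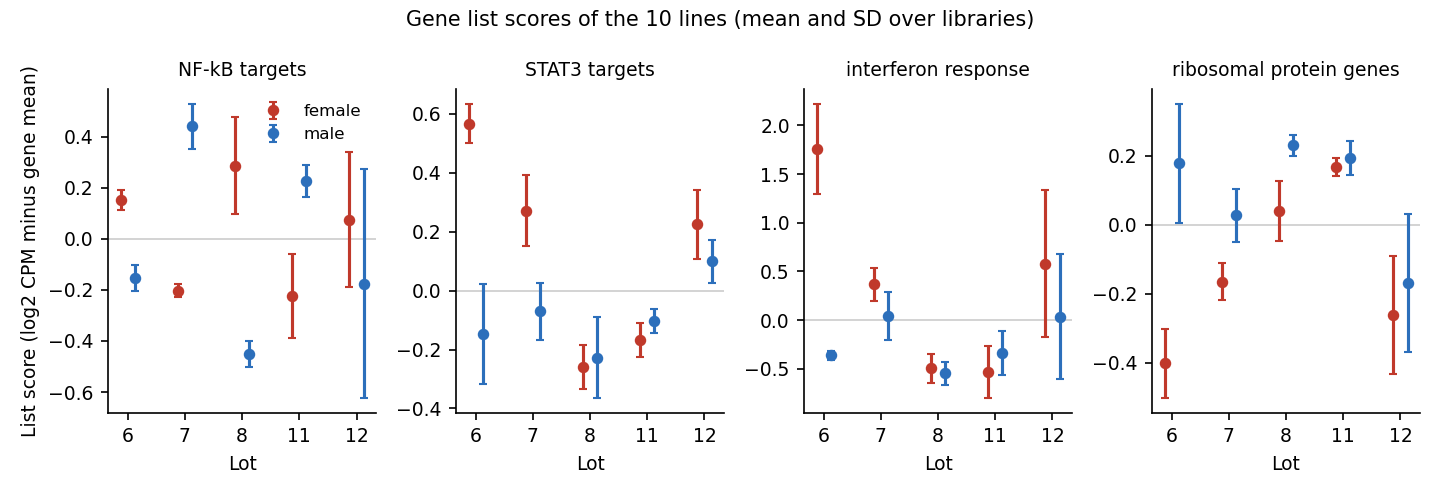
Scores of 4 gene lists in the 10 lines, as the mean log2 CPM of the list's genes minus each gene's mean over lines. Points are means and bars SD over the 3 or 4 libraries of a line, female in red and male in blue. The NF-kB score was lower in the female line in lots 7 and 11 and higher in lot 8, and the interferon score stood highest in the lot 6 female line.

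Within litters, the most genes differed in lot 6. Ezr, which links membrane to actin (chromosome 17, 6738041 to 6782784), rose from 2.19 ± 0.930 CPM in the male line to 224 ± 24.0 CPM in the female line (SD, n = 3), a log2 fold change of 6.68 ± 0.38. Crct1, a gene of the cornified envelope cluster, and Igfbp2, which binds insulin-like growth factors, rose by 6.53 ± 0.53 and 6.42 ± 0.39. Cda and Lgals3 fell by 5.92 ± 0.56 and 5.39 ± 0.46. Lgals3, which encodes galectin-3, stood at 45.0 ± 7.32 CPM in the female line against 1885 ± 80.9 CPM in the male line (SD, n = 3). In all, 3354 of 12173 genes passed, 1644 higher and 1710 lower in the female line.

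Genes of the interferon response were higher in the lot 6 female line. Of 23 members, 15 rose and 1 fell (16 adjusted over the list alone). The filter within lots needs expression in only as many libraries as the smallest line, so it kept 23 members against 14 across lots. Members may have entered because they were high in this line, so the count and the test of the list can overstate the rise. Ifit3 rose by 4.36 ± 0.90 and Ddx58, a sensor of viral RNA, by 3.69 ± 0.76. B2m, the light chain of MHC class I, rose by 0.99 ± 0.13, to 829 ± 95.8 CPM (SD, n = 3). Isg15 was at 7.39 ± 5.53 CPM in the female line and 0.109 ± 0.0953 CPM in the male line. The list had an adjusted p of 0.000118 in camera and an adjusted p = 0.269 with an estimated correlation. By library, its mean score was 1.76 ± 0.464 in the female and -0.36 ± 0.0493 in the male line (SD, n = 3). No microglia and macrophage marker exceeded 1.25 CPM in that female line.

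Extracellular matrix and mesenchymal genes split in lot 6, with 15 of 27 higher and 4 lower (21 adjusted over the list alone; adjusted p 0.00169, adjusted p = 0.38 with an estimated correlation). The actin-associated Tagln rose by 2.32 ± 0.19 and the transcription factor gene Snai2 by 3.35 ± 0.40, while the collagen genes Col1a1 and Col1a2 fell by 3.35 ± 0.36 and 4.34 ± 0.47. Of 25 components of the NF-kB and STAT3 pathways, 8 rose and 0 fell (8 adjusted over the list alone; adjusted p 0.0362, adjusted p = 0.117 with an estimated correlation). Il6st, the shared receptor chain of the interleukin-6 family, rose by 1.63 ± 0.31 and the tumor necrosis factor receptor gene Tnfrsf1a by 1.32 ± 0.28. Lifr and Osmr, receptors of the same family, were at 5.80 ± 0.765 and 12.8 ± 2.88 CPM in the female line against 0 and 0.239 CPM in the male line. Of 20 p53 targets, 6 fell and 1 rose (8 adjusted over the list alone; adjusted p 0.00852, adjusted p = 0.269 with an estimated correlation). Perp fell by 2.97 ± 0.45, Plk2 by 1.67 ± 0.22, Ccng1 by 1.54 ± 0.30 and Mdm2 by 0.99 ± 0.20. Perp and Mdm2 lie on chromosome 10 and Ccng1 on chromosome 11, whose genes were lower as a whole in the female than in the male line. Of 94 ribosomal protein genes, 82 fell and 1 rose (84 adjusted over the list alone; adjusted p 4.11e-38, adjusted p = 0.173 with an estimated correlation), among them Rpl22l1 by 2.21 ± 0.16.

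In lot 7, 659 genes were higher and 660 lower in the female line. Crct1 rose by 6.10 ± 0.46, Il1rl1, the receptor of interleukin-33, by 4.22 ± 0.34, and Mgll, a lipase gene, by 4.26 ± 0.50. Eva1b, Aebp1 and Trim47 fell by 5.88 ± 0.50, 4.40 ± 0.28 and 4.06 ± 0.28. Extracellular matrix and mesenchymal genes rose in 12 of 27 cases and fell in 1 (16 adjusted over the list alone; adjusted p 1.07e-09, adjusted p = 0.0934 with an estimated correlation). Lox, which crosslinks collagen, rose by 2.51 ± 0.24, Col5a1 by 2.11 ± 0.22, Snai2 by 2.54 ± 0.33 and the matricellular Ccn2 by 1.69 ± 0.15. NF-kB targets went the other way, with 7 of 27 lower and 2 higher (10 adjusted over the list alone; adjusted p 0.00297, adjusted p = 0.117 with an estimated correlation). Nfkbia, the inhibitor that NF-kB itself induces, fell by 1.11 ± 0.15, Vcam1 by 1.06 ± 0.18 and the chemokine genes Ccl2 and Ccl5 by 1.57 ± 0.34 and 3.01 ± 0.70.

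Stress response genes were also higher in the lot 7 female line, where 5 of 20 rose and 1 fell (10 adjusted over the list alone; adjusted p 0.000123, adjusted p = 0.181 with an estimated correlation). Chac1 rose by 2.63 ± 0.37, Asns by 0.82 ± 0.12, Herpud1 by 1.08 ± 0.17 and Atf4, the transcription factor of the integrated stress response, by 0.70 ± 0.14. Of 30 cell cycle genes, 1 fell, Tyms by 0.40 ± 0.10 (6 adjusted over the list alone; adjusted p 0.0081, adjusted p = 0.35 with an estimated correlation). Ribosomal protein genes fell in 23 of 94 cases and rose in 1 (35 adjusted over the list alone; adjusted p 2.23e-10, adjusted p = 0.583 with an estimated correlation). The X-linked escape list, which within lots also held Xist, had 3 of 7 members higher (4 adjusted over the list alone; adjusted p 0.00291, adjusted p = 0.0707 with an estimated correlation).

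In lot 8, 780 genes were higher and 608 lower in the female line. The calcium-binding S100a16 rose by 6.84 ± 0.49, the adhesion molecule gene Jaml by 5.00 ± 0.30 and Pdlim4 by 4.74 ± 0.55, whereas Sprr1a, a cornified envelope gene, fell by 5.87 ± 0.58, the carboxylesterase gene Ces1g by 3.90 ± 0.43 and Col1a1 by 3.40 ± 0.35. Of 27 NF-kB targets, 8 were higher and 2 lower (16 adjusted over the list alone; adjusted p 0.00297, adjusted p = 0.117 with an estimated correlation). The chemokine genes Cx3cl1 and Ccl2 rose by 2.27 ± 0.19 and 2.26 ± 0.36 and Ier3 by 0.90 ± 0.17, while Csf1, the macrophage growth factor, fell by 1.00 ± 0.16. Neural progenitor markers rose in 4 of 7 cases (5 adjusted over the list alone; adjusted p 0.00169, adjusted p = 0.0754 with an estimated correlation). Pax6 rose by 4.34 ± 0.58, Sox11 by 1.88 ± 0.32 and Sox2 by 0.71 ± 0.22.

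Cholesterol synthesis genes were lower in the lot 8 female line in 3 of 19 cases (6 adjusted over the list alone; adjusted p 0.0054, adjusted p = 0.535 with an estimated correlation), with Sqle falling by 0.61 and Dhcr7 by 1.11. Ribosomal protein genes fell in 42 of 94 cases and rose in 1 (45 adjusted over the list alone; adjusted p 1.34e-17, adjusted p = 0.396 with an estimated correlation). The X-linked escape list had 2 of 7 members higher (2 adjusted over the list alone; adjusted p 0.0165, adjusted p = 0.117 with an estimated correlation).

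Lots 11 and 12 had fewer differences. In lot 11, 185 genes were higher and 342 lower in the female line. Lsp1, a leukocyte actin-binding protein gene, rose by 3.40 ± 0.35, the smooth muscle gene Cnn1 by 2.60 ± 0.40 and the tubulin gene Tubb3 by 2.32 ± 0.32, while Ehbp1l1, Sprr1a and Apbb1ip fell by 3.62 ± 0.25, 3.60 ± 0.48 and 2.98 ± 0.36. Genes of senescence-associated secretion moved both ways, with 2 of 19 higher and 5 lower (7 adjusted over the list alone; adjusted p 0.0222, adjusted p = 0.301 with an estimated correlation). Igfbp5 and Igfbp3 rose by 5.28 ± 0.60 and 1.97 ± 0.35, and Fgf7 and Igfbp7 fell by 2.35 ± 0.27 and 1.75 ± 0.29. Extracellular matrix and mesenchymal genes fell in 3 of 27 cases, the opposite direction to lot 7 (8 adjusted over the list alone; adjusted p 0.0165, adjusted p = 0.58 with an estimated correlation), with Loxl2 down by 2.71 ± 0.39. Of 30 cell cycle genes, Rrm2 alone rose, by 0.50 ± 0.14 (1 adjusted over the list alone; adjusted p 0.00778, adjusted p = 0.348 with an estimated correlation). The X-linked escape list kept its call, at an adjusted p of 1.25e-05 and an adjusted p = 0.00681 with an estimated correlation, with Pbdc1 up by 0.92 ± 0.10.

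In lot 12, 212 genes were higher and 251 lower in the female line. Jaml rose by 5.22 ± 0.37, Lgals3 by 2.95 ± 0.42 and Apbb1ip by 2.81 ± 0.41, and Col1a2 and Eva1b fell by 3.74 ± 0.45 and 2.27 ± 0.44. Oxidative phosphorylation genes fell in 2 of 24 cases (2 adjusted over the list alone; adjusted p 0.0193, adjusted p = 0.642 with an estimated correlation), with Atp5b down by 0.48 ± 0.10 and Cox4i1 by 0.36 ± 0.08. Stress response genes fell in 2 of 20 cases (3 adjusted over the list alone; adjusted p 0.0187, adjusted p = 0.452 with an estimated correlation), with Herpud1 down by 0.75 ± 0.19 and Hsp90b1 by 0.55 ± 0.16. Ribosomal protein genes fell in 6 of 94 cases (11 adjusted over the list alone; adjusted p 0.00783, adjusted p = 0.892 with an estimated correlation), with Rpl34 down by 1.07 ± 0.11. The list includes Rps3a1, at 78.1 ± 7.42 CPM in the female and 546 ± 101 CPM in the male line (SD, n = 3). Its counts are uncertain, as described below. The X-linked escape list rose in 4 of 7 cases (4 adjusted over the list alone), at an adjusted p of 0.000101 and an adjusted p = 0.0107 with an estimated correlation. Kdm5c and Eif2s3x rose by 1.80 ± 0.37 and 0.98 ± 0.22.

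These within-lot counts are from edgeR's quasi-likelihood test on all 36 libraries, and DESeq2 gave 3505, 1524, 1606, 644 and 592 genes in lots 6, 7, 8, 11 and 12. Of 95 tests of a list within a lot, 24 passed camera with the preset correlation and 2 with an estimated one, the escape lists of lots 11 and 12. Xist was among the members of this list called in lots 7, 8, 11 and 12. The count of lot 12 rested on single libraries: it was 228 without male replicate 1, 265 without male replicate 2, 281 without female replicate 3, 731 without male replicate 3, and 106 when the libraries of the lot were fitted alone. With the replicate number as a block, since the numbers pair the libraries of this lot, the same libraries alone gave 665. The third libraries of both lines of lot 12 lay apart on the first principal component, at -44.5 against -20.6 and -23.0 in the female and -34.2 against -14.2 and -19.3 in the male line. Without both, an alternative chosen after seeing the data, 433 genes differed in lot 12. Without the genes of the chromosomes that shifted as a whole, lot 6 had 2082 genes.

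**Figure D3:**
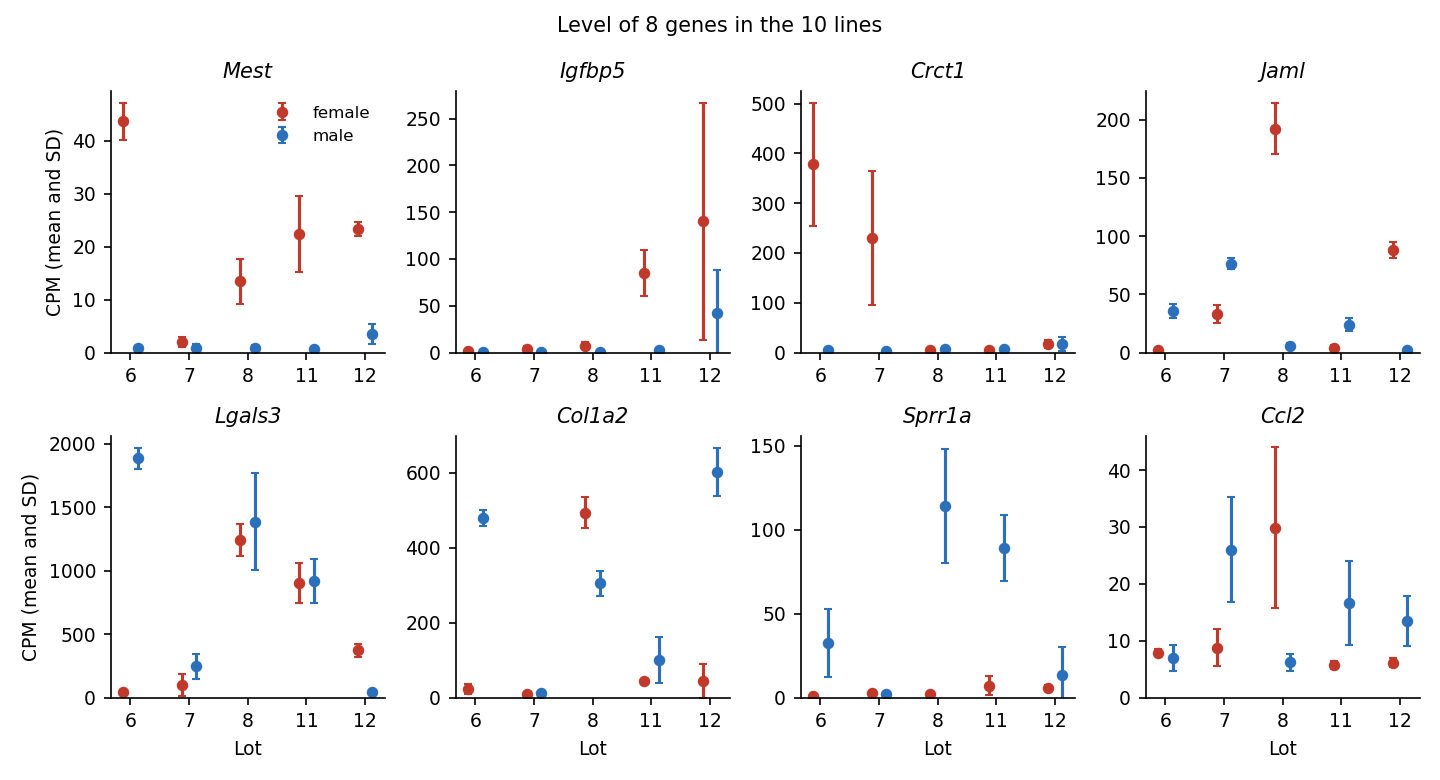
Level of 8 genes in CPM (mean and SD over the 3 or 4 libraries of each line) in female (red) and male (blue) lines of the 5 lots. Mest was 43.6 CPM in the lot 6 female line and 1.95 CPM in that of lot 7, and the sexes changed order between lots for Jaml, Lgals3, Col1a2 and Ccl2.

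Whether the difference between the sexes was the same in every litter was tested directly. Against the spread between libraries, it differed for 3643 of 12173 genes (edgeR F-test with 4 degrees of freedom; DESeq2 called 4118). Jaml was at 192 ± 22.1 CPM in the female and 5.96 ± 1.80 CPM in the male line of lot 8 (SD, n = 4), but at 1.99 ± 0.647 and 35.5 ± 6.20 CPM in lot 6 (SD, n = 3; adjusted p 5.43e-20). Prdx6, a peroxidase gene, was at 217 ± 9.58 CPM in the female and 982 ± 69.5 CPM in the male line of lot 6 (SD, n = 3), against 1020 ± 73.0 and 846 ± 35.97 CPM in lot 8 (SD, n = 4; adjusted p 2.1e-17). Crabp1, which binds retinoic acid, was at 94.7 ± 17.8 and 3005 ± 449 CPM in lot 6 (SD, n = 3) and at 1886 ± 188 and 522 ± 175 CPM in lot 11 (SD, n = 4; adjusted p 1.51e-16). Tinagl1 was at 4.54 ± 0.795 and 47.0 ± 12.0 CPM in lot 7 and at 145 ± 22.6 and 60.3 ± 20.7 CPM in lot 8 (SD, n = 4; adjusted p 1.68e-16). Without lot 6, an alternative chosen after seeing the data, 2003 genes differed.

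Rps3a1, a ribosomal protein gene, also passed (adjusted p 2.64e-18) but is uncertain, because its reads can be counted to near-identical copies. Over aligned transcript bases, the processed pseudogenes Rps3a2 and Rps3a3, named after their values were seen, matched it at 99.5% and 98.9%. Rps3a1 averaged 68.9 to 96.0 CPM in 7 lines, 1960 ± 24.8 and 1519 ± 148 CPM in the female and male lines of lot 11 (SD, n = 4) and 546 ± 101 CPM in the male line of lot 12 (SD, n = 3). Rps3a3 was lowest where Rps3a1 was highest, at 43.1 CPM in the lot 11 female line. The sum over the 3 loci ranged from 1250 to 2031 CPM, a 1.63-fold span, against 28.5-fold for Rps3a1 alone.

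**Figure D4:**
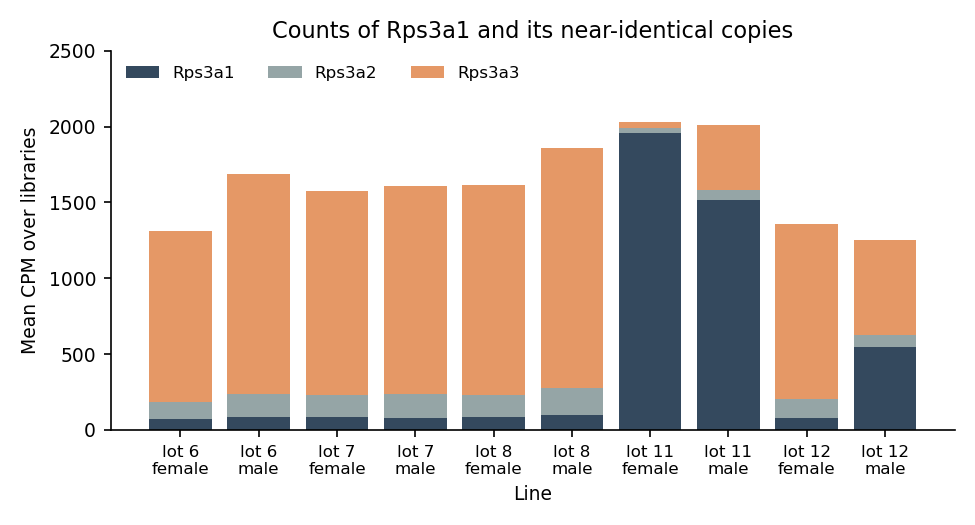
Mean CPM of Rps3a1 and its pseudogene copies Rps3a2 and Rps3a3 in each line, stacked. The share on Rps3a1 was 96.5% in the lot 11 female, 75.5% in the lot 11 male and 43.6% in the lot 12 male line, and 4.98 to 5.75% in the others.

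Lines of the same sex also differed between litters. Among the 5 female lines, 5110 genes differed (DESeq2 5467). Cst3, the protease inhibitor cystatin C, was at 5107 ± 196 CPM in lot 6 (SD, n = 3) and 813 ± 132 CPM in lot 8 (SD, n = 4; adjusted p 1.31e-21). Serpinf1, which encodes the secreted factor PEDF, was at 833 ± 15.2 CPM in lot 6 (SD, n = 3) and 10.5 ± 2.21 CPM in lot 8 (SD, n = 4; adjusted p 3.13e-21). Among the 5 male lines, 3742 genes differed (DESeq2 4268). The contractile genes Tpm2 and Acta2 were at 833 ± 113 and 10930 ± 1426 CPM in lot 12 (SD, n = 3) against 42.7 ± 8.45 and 1998 ± 383 CPM in lot 8 (SD, n = 4; adjusted p 2.24e-19 and 1.92e-18). Ccn2 was at 2024 ± 397 and 222 ± 29.0 CPM in the same lots (adjusted p 2.61e-18), and F3, the initiator of coagulation, at 225 ± 34.8 and 21.7 ± 6.20 CPM (adjusted p 9.27e-18).

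How far the litters shared their differences between the sexes was compared for each pair of lots. Across 11728 autosomal genes, which are not independent replicates, the fold changes of a pair of lots correlated at a median Pearson r of 0.021 over the 10 pairs (Spearman 0.054). Lots 6 and 7 stood apart, with r = 0.27 (Spearman 0.28) and r = 0.44 among the 3314 most expressed genes. They shared 705 called genes, of which 627 had the same direction, where independent lists would give 175 in the same and 175 in the opposite direction. Lots 6 and 8 shared 408 in the same and 234 in the opposite direction (184 and 185 by chance), lots 6 and 12 shared 165 and 86 (61.2 and 60.8 by chance), and lots 8 and 11 shared 108 and 78 (27.3 and 29.7 by chance). In lots 7 and 8, 138 were in the same and 173 in the opposite direction (72.1 and 72.2 by chance). Opposite directions were also more common in lots 7 and 11 (73 same, 87 opposite) and lots 7 and 12 (67 and 78). The remaining pairs were lots 6 and 11 (129 and 117), lots 8 and 12 (91 and 64) and lots 11 and 12 (52 and 38). No autosomal gene was called in the same direction in all 5 lots. The 5 called higher in 4 lots and lower in none were Mest, Csdc2, Tmx2, Lurap1l and 2900011O08Rik, named after their values were seen, and 13 were called lower in 4 and higher in none, 7 of them on chromosome 10. Of the summed squares of log2 CPM, 28.3% lay between lots, 6.44% between sexes, 20.7% in their combination and 44.6% between libraries of a line, on 4, 1, 4 and 26 degrees of freedom. Per degree of freedom, the shares were 7.07%, 6.44%, 5.16% and 1.72%.

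The genes of whole chromosomes shifted together in some lines, a pattern looked for after seeing the data. In lot 6, the 147 genes of chromosome 14 had a median log2 fold change of -0.82 in the female line, and 85.7% of them lay below the median of all genes. Chromosome 10 was at -0.63 and chromosome 11 at -0.39, whereas chromosome 2 was at 0.34 and chromosome 7 at 0.15. Each of these 5 medians lay outside those of 10000 random sets of as many genes. In lot 12, chromosomes 10 and 15 were at -0.36 and -0.31, in lot 7 chromosome 9 at -0.29, and in lot 11 chromosome 19 at -0.25. Chromosome 10 was also at -0.18 in lot 7 and -0.11 in lot 11. Such differences can come from either line of a lot. Against the median of the 10 lines, chromosome 10 was at 0.41 in the lot 6 male and -0.22 in the lot 6 female line. In lot 12, chromosomes 10 and 15 were at 0.25 and 0.27 in the male and -0.049 and -0.0012 in the female line. The number of chromosomes outside all random sets was 9, 12, 7 and 8 in lots 7, 8, 11 and 12. These counts include small shifts: the medians of lot 8 ran only from -0.17 to 0.20, and chromosome 2 in lot 7 lay outside at 0.061. The random sets draw genes singly, as if independent, so a median outside them does not by itself show a change of a whole chromosome. Genes on the shifted chromosomes of lot 6 were called in 32.1% of cases and genes elsewhere in 25.5%.

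**Figure D5:**
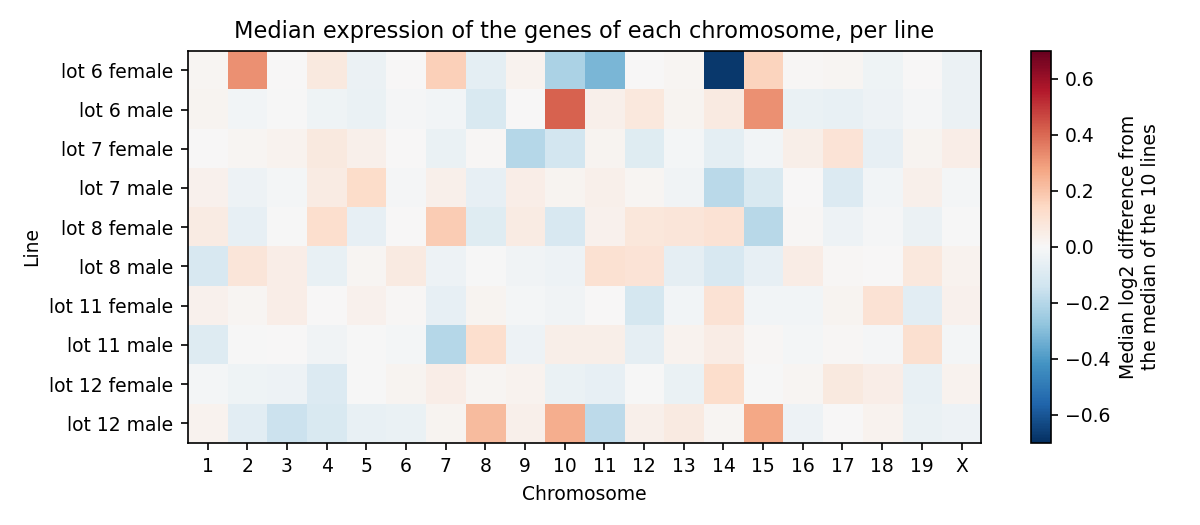
Median log2 difference of the genes of each chromosome from the median of the 10 lines, per line (rows) and chromosome (columns), on a colour scale from blue (lower) to red (higher). The lowest value is chromosome 14 in the lot 6 female line, at -0.68.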

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

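The tests on chromosome 14, on Xist and on the interferon response were chosen after the result was seen, except that of a single library, and so was the comparison of the lot 12 splits by pairs, while the other splits of the samples were planned before.

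A line stood apart from the other 4 of its sex in 6 of 57 groups of 5 lines, and chance gives about 1 in 20 groups, or 2.85. The groups covered only chromosomes 2, 10, 11 and 14, picked after the chromosome shifts were seen. The 6 groups therefore do not measure an excess over chance. The lot 6 female line was lowest among female lines in the score of X-linked escape genes, at -0.33, in Nf1, at 0.70 CPM, in the level of chromosome 11, at -0.322, and in that of chromosome 14, at -0.678. It was highest in the level of chromosome 2, at 0.317. The lot 12 male line was lowest among male lines for chromosome 11, at -0.183. The difference between the sexes itself differed between lots for 3643 genes, with adjusted p of 5.43e-20 for Jaml, 2.64e-18 for Rps3a1, 2.1e-17 for Prdx6, 1.51e-16 for Crabp1 and 1.68e-16 for Tinagl1 (edgeR).

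Chromosome 14 genes were lower in the lot 6 female line than in its male line. A few strongly lower genes cannot account for this, since 85.7% of the genes of the chromosome lay below the median of all genes, nor can library depth, since the median was -0.813 after thinning. The loss of a copy of the chromosome may account for it, as the highest median of the 3 sections of the chromosome was -0.724. DNA was not measured, and no biological explanation other than the loss of a copy was tested.

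Xist was near the floor in the lot 6 female line, with 5, 4 and 0 counts in its libraries, and 1 library of another line, lot 8 female replicate 3, had 1 count. A swap with a male sample that kept its Y-linked transcripts is excluded by a Y-linked sum of at most 1.32 CPM. That sum cannot exclude a male sample that had lost them. Library depth is excluded by a count that was 11.4% of the one predicted from the lowest other female line. X-linked genes outside the escape list had a median log2 fold change of 0.0617, which argues against both X chromosomes being active. A single X chromosome may account for it, as the median of the escape list without Xist was -0.172 in lot 6 and 0.32 to 0.75 in the other lots. Of the 6 genes, Kdm6a and Kdm5c were higher in lot 6 without passing (0.51 ± 0.62 and 0.44 ± 0.37) and Utp14a was lowest, at -1.31 ± 0.23, and no biological explanation beyond the number of X chromosomes was tested.

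Interferon response genes were higher in the lot 6 female line, at an adjusted p of 0.000118 in camera but an adjusted p = 0.269 with an estimated correlation. Microglia and macrophages are argued against by a highest marker mean of 1.25 CPM, and a single library by the lowest female library lying 1.79 above the highest male library. Library scores over 23 members differed by 2.12 in lot 6 and by 0.324, 0.0501, -0.192 and 0.546 in lots 7, 8, 11 and 12. This argues against a difference between the sexes of the same size in every lot. Scores of the summed lines over 14 members differed by 1.59 in lot 6 and by 0.498, 0.148, -0.644 and 0.36 in the others. The other lots spread more widely there, so that argument depends on the score. Some of the 23 members may also have passed the filter only through the lot 6 female line. A smaller part of sex cannot be told apart from differences between lines, as the lowest difference among the 5 lots was -0.192 by library and -0.644 by summed line. A viral or other stimulus of the culture was not tested.

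Across lots, the real split called 0 genes with edgeR (841 at an unadjusted p under 0.05, DESeq2 60), so each of the 100 splits of the 10 sums called at least as many by construction and the count of splits decides nothing, nor does that of 100 for autosomal genes. The highest other split called 72 genes, and 71 when autosomal genes alone were counted. For lists, 95 of 100 splits called as many, with 2 real and 7 in the highest other, so chance is not excluded for the lists. The 16 splits that swap the sexes within lots are too few for a share under 0.05: at an unadjusted p under 0.05, 841 genes were real and 755 in the highest other, all 16 called 0 genes, and 2 lists were called by the real split and 2 to 6 by the others. Within and between lots, the splits regroup the libraries of single lines, so they test only the spread between libraries and do not exclude chance differences between single lines. Chance in the spread between libraries is excluded for lot 7, where 1 of 35 splits gave as many genes (1319, highest other 23), for lot 8 (1 of 35; 1388 and 46) and for lot 11 (1 of 35; 527 and 3). Lots 6 and 12 have 10 splits each, too few for a share under 0.05, with 3354 real and 0 in the highest other, and 463 and 291. The replicate numbers of lot 12 pair its libraries: the 3 other splits that part all 3 pairs called 0 genes, and the 6 that part 1 pair called 1 to 291. It is also excluded, for libraries alone, for the difference between lots (1 of 100; 3643 and 2298), among female lines (1 of 100; 5110 and 1583) and among male lines (1 of 100; 3742 and 854).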

How the results depend on the processing

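The alternatives without lot 6, without the genes of shifted chromosomes and without the third libraries of lot 12 were chosen after seeing the data, and the others before.

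Across lots, edgeR called 0 genes (841 at an unadjusted p under 0.05). The counts of all and of autosomal genes were 3 and 1 without a filter, 60 and 52 with DESeq2, 412 and 393 with limma voom, 1269 and 1210 with 36 libraries as replicates, 658 and 626 with sex alone, 909 and 866 with the replicate block, 1 and 0 without the lot block, and 1 and 0 with thinned counts. Like the fit with 36 libraries as replicates, those with sex alone and with the replicate block take libraries of a line for separate litters. Leaving out a library or lot gave 0 to 1 genes, the 1 without lot 7 female replicate 4, and 0 to 0 autosomal genes. Called lists numbered 0 with an estimated correlation, 0 with fry's directional and 0 with its mixed test, and 1 to 5 without a lot: 1 without lot 7, 4 without lot 8 and 5 without lot 11. Within lots, 2 of 24 calls of lists held with an estimated correlation.

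Lot 12 had 106 genes with its own libraries alone, 665 with these and the replicate block, 228 to 731 without 1 library, and 433 without the third libraries of both lines, where 3869 genes differed between lots. Lot 6 had 2082 without the genes of shifted chromosomes, where fewer genes were tested, and 2003 genes differed between lots without lot 6. The NF-kB score difference was -0.0321 with genes at unit SD and -0.211 to 0.215 without a lot, and its correlation with STAT3 -0.24 to 0.0854. The STAT3 score difference was 0.136 to 0.297 without a lot, lowest without lot 6. Values that changed sign, none past the threshold, were Nf1 (0.0131 with thinned counts, -0.38 to 0.23 in leave-outs), Nfkb2 (0.0462 without TMM, -0.24 to 0.0653), Nfkb1 (-0.21 to 0.0242), Relb (-0.31 to 0.50), Cxcl1 (-1.01 to 0.32) and Lif (-0.50 to 0.34). Lif was 0.0626 without TMM, 0.26 with voom, 0.0482 with 36 libraries, 0.40 without the lot block, 0.38 with sex alone, 0.0229 with the replicate block and 0.040 with thinned counts. Except where fewer genes or libraries were tested, the cause was not tested. Of 7534 values of 241 results on named genes, 7238 kept direction and side of the threshold, 54 fell short of it, 211 passed it and 31 changed sign. The results that fell short under some alternative were 9 of 21 in lot 12, 4 of 26 in lot 8 and 3 of 22 in lot 11. Depth limits genes near the floor of 0.397 to 0.688 CPM, such as Nf1 and Xist.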

Other observations

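Of the tests below, the alternative without the third libraries of lot 12 was chosen after the result was seen.

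No list below passed camera across lots with the preset correlation, which does not show that the sexes were alike. Extracellular matrix and mesenchymal genes had a median log2 fold change of 0.35, with 18 of 27 members above 0 (adjusted p 0.0583), and interferon response genes a median of 0.36, with 10 of 14 above 0 (adjusted p 0.0806). Genes of senescence-associated secretion had 10 of 17 above 0 (adjusted p 0.232), and Igfbp5, which binds insulin-like growth factors, was the 1 member that passed when adjusted over the list alone. Of 10 alternatives for each list, the matrix list passed in 4, the interferon list in 2 and the senescence list in 1. Of markers, neural progenitor genes had a median of 0.71, with 5 of 6 above 0 (adjusted p 0.232), astrocyte genes 6 of 8 (adjusted p 0.711) and fibroblast and meningeal genes 2 of 6 (adjusted p 0.851).

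Cell cycle genes had 20 of 30 members above 0 (adjusted p 0.764), p53 targets 9 of 20 (adjusted p 0.798) and oxidative phosphorylation genes 10 of 24 (adjusted p 0.391). Cholesterol synthesis genes had 11 of 19 above 0 and stress response genes 13 of 20 (adjusted p 0.851 for both). For Ras/MAPK feedback genes (10 of 22, adjusted p 0.711) the median was -0.09 and the mean 0.01, and for hypoxia and glycolysis genes (8 of 20, adjusted p 0.764) -0.07 and 0.17. For mitochondrial transcripts (5 of 10, adjusted p 0.878) the mean was -0.02 and the test's direction was up. Except for Igfbp5, 0 members of these lists passed when adjusted over the list alone, and 0 over all genes.

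Fewer than 5 members were tested for Y-linked genes (3 of 8), oligodendrocyte lineage (2 of 10), neuron (3 of 10), microglia and macrophage (1 of 12), pericyte and smooth muscle (2 of 8), endothelial (1 of 9) and ependymal markers (2 of 5), so these lists had no test. Their most abundant members were Cnp at 11.5 CPM, Tubb3 at 15.7 CPM, Cd68 at 3.25 CPM, Acta2 at 6086 CPM, Flt1 at 8.69 CPM and Rsph1 at 2.01 CPM.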
